A study of Mus musculus with 12 samples.

How the data were processed

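Whole orthotopic tumours of 4T1 and EMT6 mammary carcinoma cells (50 µl injected into 6-week-old female BALB/c mice) were collected when control tumours reached about 2 cm3. Mice had received vehicle (90% corn oil and 10% DMSO) or A-196 at 25 mg/kg by daily gavage, with 3 tumours in each of 4 groups. Per the labels, tumours were dissociated with collagenase and hyaluronidase, frozen, freed of dead cells on Percoll and loaded at about 26000 cells per library on a droplet platform for 5′ single-cell RNA, with 1 library per tumour. The labels also carry a genotype tag (WGD− or WGD+) that follows treatment exactly and whose meaning they do not state, so treatment and this tag could not be told apart.

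The deposited matrices hold raw UMI counts per gene and cell barcode for 32285 genes, with no normalization. Per the file headers the authors made them with Cell Ranger 6.1.2, while the submitters' processing notes list Cell Ranger 7.0.1, both on mouse build mm10. Gene positions came from GENCODE release M21 on GRCm38. Cell labels of the authors were not analysed here, and every class was rebuilt from the counts.

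Barcodes with at least 500 UMIs, at least 250 genes and at most 15% mitochondrial UMIs were kept (250511 of 269149). Doublets were ranked by scrublet within each library, and the highest scores were removed at 0.4% per 1000 cells (21719 cells), because scrublet's own threshold called 3 cells in EMT6 vehicle replicate 1 and 0 in EMT6 A-196 replicate 2. Each model was clustered on its own, without integration: counts were scaled to 10000 per cell and logged, 3000 variable genes were taken without mitochondrial, ribosomal, haemoglobin, cell-cycle and receptor genes, and 40 principal components, 20 neighbours and Leiden resolution 1.0 gave 23 clusters in 4T1 and 20 in EMT6. Clusters were named from markers of 18 classes. Clusters led by nuclear-retained RNAs or by osteoclast genes (2 in 4T1, 2 in EMT6) and 1 EMT6 cluster that mixed plasmacytoid and T cell genes stayed unnamed, although each held markers of a class.

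For each library and class with at least 50 cells, counts were summed (pseudobulk) and tested with edgeR quasi-likelihood fits (TMM scaling, filterByExpr, robust dispersion) in 1 model per class over all 12 libraries. Contrasts were A-196 against vehicle in 4T1, in EMT6, their average, and their difference (EMT6 minus 4T1). Genes passed at a Benjamini-Hochberg adjusted p under 0.05. CPM (counts scaled by TMM to the library size) are group means with SD over libraries. Log2 fold changes are those of the fit and carry its SE. A prior count of 2 entered only log2 CPM, used for list tests and for separation of libraries. Genes named for tumour-like cells were the 12 with the largest fold change in each direction that passed, reached a log2 CPM of 4 and separated the libraries of the groups, or, where fewer passed, all of these and then the smallest p up to 20. For differences and other classes up to 5 genes per direction were named, for each list the 4 members with the smallest p, and always Kmt5a, Kmt5b and Kmt5c. The text prints a selection of these, and some single-gene values are not reported here.

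There were 39 gene lists fixed before the data were examined. For tumour-like cells there were 28, of which 27 could be tested; 11 common lists plus lists of the class itself were used elsewhere. They were tested with camera at a preset correlation of 0.01, adjusted over lists and contrasts within a class, with camera at an estimated correlation, and with fry, which asks whether a list moves on balance in a single direction. Members were also adjusted over the list alone.

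Shares of classes, of cycling cells and of keratin-positive cells were compared by exact two-sided permutation of treatment within each model. That gives 400 relabelings and a smallest p of 0.005 for the average, and 20 relabelings and a smallest p of 0.1 for a single model. Cycling and keratin shares were counted after thinning cells to 2000 UMIs, with the same shares in macrophage-like cells as background. Groupings of the libraries, the real one included (all 10 for a single model, 100 drawn for both), were put through the same tests. Depth was 14585211 to 79202397 UMIs per library. A change in a gene that did not pass is not excluded, because the fit missed some changed genes at every fold given below.

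The fit was tested on simulated data with fold changes added to a share of genes. Each gene was drawn on its own, without variation that genes share. In 4T1 tumour-like cells it recovered 48.5%, 76.1% and 90.8% of changed genes at folds of 1.5, 2 and 4, in EMT6 47.0%, 74.6% and 87.7%, and on average 69.7%, 89.6% and 95.4% of 13757 genes' changed members, with 8, 10 and 15 false calls.

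Alternatives tried were DESeq2, RLE scaling, no filter and a stricter filter, separate fits per model, tumour numbers as a block, each library left out in turn, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), no doublet removal, Leiden 0.5 and 2.0, tumour-like cells without host UMIs, equal numbers of tumour-like cells, other thinning depths, host cells as denominator, and edgeR on cell numbers. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2 and matplotlib 3.10.9, with seed 1.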

Results

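Single-cell RNA was measured in whole orthotopic mammary tumours of female BALB/c mice to ask what A-196 does to the tumour and its host cells. 4T1 and EMT6 are mouse mammary carcinoma lines that grow in BALB/c mice. A-196 inhibits SUV420H1 and SUV420H2 (genes Kmt5b and Kmt5c), the enzymes that carry lysine 20 of histone H4 from the monomethylated to the dimethylated and trimethylated state. Each model had 3 tumours given vehicle and 3 given A-196 at 25 mg/kg daily, so there were 12 libraries in 4 groups of n = 3. The libraries held 269149 barcodes and 559025989 unique molecular identifiers (UMIs), and 228792 cells were kept (122992 from 4T1, 105800 from EMT6; 11931 to 25525 per library).

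Depth differed between libraries. The 4T1 vehicle libraries held 53578342, 32302645 and 67376698 UMIs, and the 4T1 A-196 libraries 27981659, 60207147 and 55681605. The EMT6 vehicle libraries held 34089576, 44170083 and 43366988 UMIs, and the EMT6 A-196 libraries 46483638, 14585211 and 79202397. EMT6 A-196 replicate 2 was the shallowest, with a median of 639 UMIs per barcode where EMT6 A-196 replicates 1 and 3 had 1625 and 2794. In that library 39.2% of barcodes (8120 of 20697) held fewer than 500 UMIs, and no other library had any.

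Tumour-like cells made up 57.4% of kept cells in 4T1 (70649) and 67.6% in EMT6 (71562). Monocyte and macrophage-like cells followed with 26.7% and 21.03%, fibroblast-like cells with 4.60% and 3.40%, neutrophil-like cells with 2.65% and 0.941%, and endothelial-like cells with 1.14% and 0.567%. Dendritic-like cells, named in 4T1 only, were 2.07% of 4T1 cells, and T and NK-like cells were 1.12%. The T and NK-like class was named from T cell markers. NK cells had markers of their own, and no cluster took their name, so NK cells in this class are not shown. Xist, expressed by host cells of female mice, was detected in 1.22% of tumour-like cells in 4T1 and 0.599% in EMT6, against 12.8% to 51.3% in the host classes of 4T1 and 5.22% (neutrophil-like) to 30.0% in those of EMT6. Tumours had been dissociated, frozen and passed over Percoll to remove dead cells, so shares describe the cells that survived these steps.

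No class changed its share of cells past the threshold. Tumour-like cells were 60.7% ± 7.80 (SD, n = 3) in 4T1 vehicle and 54.5% ± 4.06 in 4T1 A-196 tumours, and 69.0% ± 1.72 and 68.6% ± 14.8 in EMT6 (average difference −3.30 percentage points, exact stratified permutation p = 0.5). Macrophage-like cells were 24.4% ± 7.57 and 28.8% ± 3.72 in 4T1, and 19.5% ± 2.09 and 20.6% ± 12.5 in EMT6 (average difference 2.74 points, exact p = 0.55). The shallow EMT6 A-196 replicate 2 held 6.44% macrophage-like and 85.2% tumour-like cells, and without it these average differences were 6.27 and −7.44 points. Fibroblast-like cells went from 4.96% ± 1.09 to 4.25% ± 0.403 in 4T1 and from 3.60% to 3.20% in EMT6. Plasmacytoid dendritic-like cells of 4T1 did not overlap between groups, with 0.256% ± 0.145 in vehicle and 0.665% ± 0.0487 in A-196 tumours (n = 3, exact p = 0.1, the smallest that 3 against 3 allows, adjusted p = 0.786). The smallest adjusted p over all shares was 0.475.

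**Figure D1:**
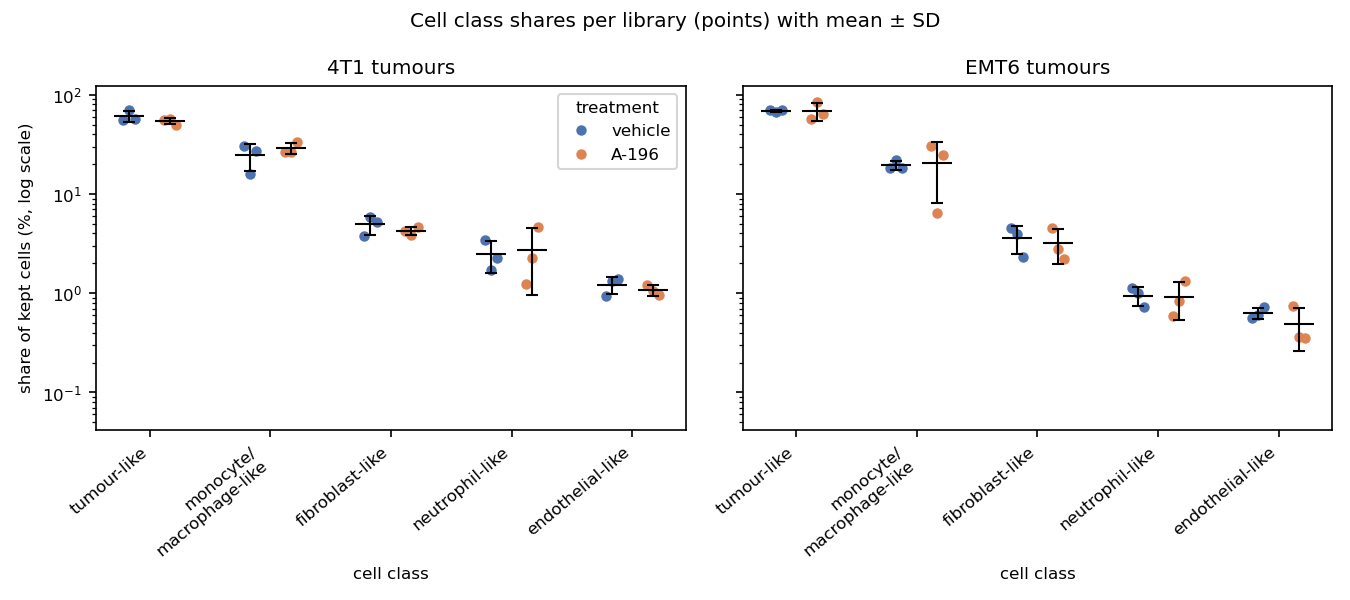
Share of kept cells in percent (vertical axis) on a log scale for the 5 largest classes named in both models, with a point per library and bars for mean and SD (n = 3). In EMT6 A-196 tumours macrophage-like shares ran from 6.44% to 30.3% and tumour-like shares from 56.9% to 85.2%.

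In 4T1 tumour-like cells the genes with the smallest p under A-196 included the lysosomal peptidases Tpp1 and Lgmn, the ceramidase Asah1, the stress sensor Ern1 (IRE1) and the hypoxia gene Bnip3, all higher. Tpp1 went from 24.3 ± 1.64 to 34.0 ± 2.82 CPM (library-scaled counts, SD, n = 3), a log2 fold change of 0.48 ± 0.09 (SE, adjusted p = 0.337). Zfand2a went from 29.4 ± 1.04 to 46.2 ± 7.35 CPM (0.65 ± 0.11, adjusted p = 0.258) and the amino acid transporter Slc38a2 from 126 ± 6.51 to 182 ± 16.3 CPM (0.53 ± 0.09, adjusted p = 0.258). Fam110a went from 45.5 ± 1.38 down to 30.8 ± 2.78 CPM (−0.56 ± 0.10, adjusted p = 0.258). Bnip3 was higher by 0.63 ± 0.13, Asah1 by 0.37 ± 0.08, Lgmn by 0.59 ± 0.12, Ern1 by 0.41 ± 0.09, Atp6ap2 by 0.44 ± 0.10 and the epithelial factor Ovol1 by 0.78 ± 0.17 (adjusted p = 0.349 each). Of 13901 genes, 0 passed with edgeR, 1025 had an unadjusted p under 0.05, and DESeq2 called 35. Of the genes tested, 1852 (13.3%) had every A-196 library beyond every vehicle library. Chance gives 10% on average over groupings, and the spread of this share between groupings was not computed.

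Several gene lists passed in 4T1 although no single gene did. By camera with its preset correlation 13 of the 27 lists tested were called (5 higher, 8 lower), each with an adjusted p = 0.92 with an estimated correlation. Fry called 0, with a smallest adjusted p = 0.461 over all 4 contrasts and 5 lists at an unadjusted p under 0.05 in 4T1. The count stayed 13 without the shallow EMT6 library, and other groupings of the same 6 libraries called up to 15 lists. A UMI of any of 8 host genes was found in 11.5% ± 1.62 of tumour-like cells of vehicle and 15.3% ± 1.17 of A-196 tumours (n = 3, exact p = 0.1, the smallest possible). This share was not thinned to equal depth. Other host genes summed to 1323, 1348 and 1325 CPM in the vehicle and 2112, 750 and 1552 CPM in the A-196 libraries. Of 18 host genes 14 were higher and 4 lower (median 0.24), none past the threshold, so a difference in host-cell RNA was not shown.

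Endoplasmic reticulum chaperones were higher in 4T1. All 17 measured members of the ATF6 list were higher (median log2 fold change 0.15, adjusted p = 6.5e-05, and 0.92 with an estimated correlation), and 1 passed adjusted over the list alone. Pdia4 led with 0.32 ± 0.09, followed by Hsp90b1 (0.30 ± 0.11) and Canx (0.19 ± 0.07). In the IRE1 to XBP1 list 16 of 20 members were higher (median 0.09, adjusted p = 0.0024), and 2 passed adjusted over the list alone, with Ern1 at 0.41 ± 0.09 and Dnajb9 at 0.48 ± 0.12. The PERK to ATF4 list did not pass (median 0.06, 15 of 25 higher, adjusted p = 0.44), nor did heat shock genes (median 0.08, 12 of 15 higher, adjusted p = 0.080) or the proteasome (median −0.05, 16 of 22 lower, adjusted p = 0.084). In the same comparison the share of tumour-like cells with a host UMI was higher by 3.76 percentage points.

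Hypoxia and glycolysis genes were higher in 4T1 in 22 of 25 members (median 0.28, adjusted p = 1.4e-07), with Bnip3 0.63 ± 0.13, Car9 0.65 ± 0.15, P4ha1 0.61 ± 0.15 and Pdk1 0.43 ± 0.12, and 6 passed adjusted over the list alone. A tumour-like cluster led by Bnip3, Ero1l and Car9 held 300 of 10376, 103 of 13077 and 185 of 13367 tumour-like cells in the vehicle libraries. In the A-196 libraries it held 376 of 8649, 598 of 14679 and 449 of 10501. Whether this make-up accounts for the list change was not tested. All 25 extracellular matrix genes were higher (median 0.34, adjusted p = 3.3e-04), among them Fn1 by 0.42 and Plod2 by 0.33, and 0 passed adjusted over the list alone. Type II interferon genes were higher in 18 of 19 (median 0.21, adjusted p = 0.028), with Cxcl10 at 0.42 and Gbp2 at 0.39. Cholesterol synthesis genes were lower in 21 of 22 (median −0.23, adjusted p = 6.9e-06), with Idi1 −0.56 ± 0.16 and Cyp51 −0.28, and 4 passed adjusted over the list alone. These adjusted p were each 0.92 with an estimated correlation.

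DNA replication genes were lower in 4T1 tumour-like cells: 37 of 41 S phase genes (median −0.22, adjusted p = 2.1e-09), with Gins2 −0.39 ± 0.11, Rad51ap1 −0.72 ± 0.21 and Mcm5 −0.37, though 0 passed adjusted over the list alone. G2 and mitosis genes were lower in 42 of 52 (median −0.11, adjusted p = 2.3e-04, with Hmgb2 −0.35, Cdk1 −0.23), and DNA damage and repair genes in 17 of 22 (median −0.12, adjusted p = 0.019, with Parp1 −0.25). So were H4K20 and heterochromatin regulators in 12 of 15 (median −0.13, adjusted p = 0.041, with Cbx1 −0.13, Hat1 −0.17). Oxidative phosphorylation (median −0.09, 19 of 25 lower, adjusted p = 0.0040, with Ndufb8 −0.24), ribosomal proteins (median −0.11, 27 of 28 lower, adjusted p = 5.0e-05, with Rps15 −0.34 ± 0.09) and NF-kB cytokines (median −0.26, 16 of 24 lower, adjusted p = 0.017, with Lif −0.91 ± 0.29, Cxcl1 −0.59 ± 0.20) were lower too. Each was at adjusted p = 0.92 with an estimated correlation.

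The immune lists not called in 4T1 were type I interferon (median 0.06, adjusted p = 0.94), MHC class I (0.10, adjusted p = 0.26) and MHC class II (0.12, adjusted p = 0.95). The p53 targets were not called (0.11, adjusted p = 0.46), and Mdm2 (0.36 ± 0.10) was the 1 member past the threshold adjusted over the list alone. Also not called were spindle checkpoint (−0.08, adjusted p = 0.10), fatty acid synthesis (−0.02, adjusted p = 0.72), dissociation stress (0.02, adjusted p = 0.84) and histone genes (median −0.11 and test down, mean 0.03, adjusted p = 0.16). The 2-cell-stage and germline list could not be tested because only Rhox5 and Sp110 of 22 members were measured. Rhox5 was at −1.37 ± 0.40 (adjusted p = 0.47) and Sp110 at −0.31 in 4T1, and they were at −0.13 and 0.00 in EMT6.

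In EMT6 tumour-like cells 4 genes rose. Sgcb, a sarcoglycan of the dystrophin complex, went from 2.49 ± 0.19 to 4.68 ± 0.194 CPM (n = 3, log2 fold change 0.92 ± 0.12, adjusted p = 0.011). The centromere protein gene Cenpv went from 32.7 ± 1.92 to 51.4 ± 3.03 CPM (0.66 ± 0.09, adjusted p = 0.011), the kinase gene Stk39 from 13.6 ± 0.318 to 22.3 ± 2.75 CPM (0.73 ± 0.10, adjusted p = 0.021), and Bmp8a from 5.88 ± 0.97 to 11.9 ± 1.6 CPM (1.02 ± 0.16, adjusted p = 0.036). On mm10 these protein-coding genes lie at chr5 73632749 to 73647790 (Sgcb, ENSMUSG00000029156, minus strand), chr11 62524946 to 62539261 (Cenpv, ENSMUSG00000018509, minus), chr2 68210445 to 68472268 (Stk39, ENSMUSG00000027030, minus) and chr4 123312645 to 123343252 (Bmp8a, ENSMUSG00000032726, minus). Next by p were Lbh (−0.81 ± 0.13) and Rexo2 (0.45 ± 0.07), each at adjusted p = 0.054. They were followed by Eno2 (−0.77 ± 0.14, adjusted p = 0.110) and H2afx (0.49 ± 0.10, adjusted p = 0.164). Cdkn2a went from 58.1 ± 3.02 to 121 ± 42.7 CPM (1.07 ± 0.21, adjusted p = 0.18).

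The EMT6 gene count depended on single libraries and on the fit, and a separate fit of EMT6 called 0. In the joint fit it was 14 without the shallow EMT6 A-196 replicate 2, 11 without EMT6 A-196 replicate 3 and 7 without EMT6 vehicle replicate 3, and 0 without EMT6 vehicle replicate 1, EMT6 vehicle replicate 2 or EMT6 A-196 replicate 1. It was 6 without 4T1 vehicle replicate 1 and 2 without 4T1 A-196 replicate 2, which enter through the shared dispersion. At an unadjusted p under 0.05 there were 1502 genes, and DESeq2 called 138. Every A-196 library lay beyond every vehicle library in 2456 genes (17.7%). Chance gives 10% on average over groupings, whose spread was not computed. Other groupings of the same 6 libraries called up to 44 genes.

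In EMT6 7 lists were called with the preset correlation (5 higher, 2 lower), each with an adjusted p = 0.92 with an estimated correlation. There were 6 without EMT6 A-196 replicate 2 and 11 without EMT6 vehicle replicate 3. Fry called 0 lists, with 0 at an unadjusted p under 0.05. Other groupings of these 6 libraries called up to 14 lists. ATF6 genes were higher in 13 of 17 (median 0.08, mean 0.22, adjusted p = 0.010), with Sdf2l1 0.46 ± 0.10, Creld2 0.29 ± 0.09 and Hyou1 0.23 ± 0.10, and 2 passed adjusted over the list alone. Proteasome genes were higher in 20 of 22 (median 0.09, adjusted p = 5.8e-04, with Psmb5 0.26, Psma4 0.22). The share of these cells with a host UMI was 6.25% ± 0.916 in vehicle and 7.93% ± 2.82 in A-196 tumours (n = 3, exact p = 0.5).

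Replication genes were higher in EMT6: 35 of 41 S phase genes (median 0.16, adjusted p = 6.8e-05, with Tyms 0.31, Rfc2 0.28, Mcm4 0.27). So were 44 of 52 G2 and mitosis genes (median 0.08, adjusted p = 0.0024, with Hmmr 0.33, Cdk1 0.25) and 18 of 22 DNA damage genes (median 0.07, adjusted p = 0.011, with H2afx 0.49 ± 0.10). Without the shallow library these 3 medians were 0.03 (adjusted p = 0.94), 0.01 (adjusted p = 0.80) and −0.0020 (adjusted p = 0.96). Tumour-like clusters led by cell-cycle genes were also counted. The cluster led by Slpi, Pttg1 and Cdkn3 held 1180, 1329 and 845 cells in the vehicle and 321, 395 and 548 in the A-196 libraries. The cluster led by Hist1h1b and Hist1h2ap held 1109, 1032 and 1319 in vehicle and 1014, 1430 and 1348 in A-196 libraries. The cluster led by Cdc20, Pttg1 and Cenpa held 1493, 1169 and 1346 in vehicle and 923, 5530 and 1254 in A-196 libraries. Its count exceeded the vehicle range only in the shallow library, with 5530 of 10165 tumour-like cells. Cells of this cluster held a median of 965 UMIs, 0.682 of the library median on average. Whether shallow cells collect there was not tested. Hypoxia genes were lower in 23 of 25 (median −0.19, adjusted p = 2.7e-05), with Ankrd37 −0.61 ± 0.15, Bnip3 −0.49 ± 0.13 and Bnip3l −0.40 ± 0.11, and 5 passed adjusted over the list alone. Without the shallow library the hypoxia median was −0.10 (adjusted p = 0.0015). A tumour-like cluster led by Adm, Ankrd37 and Ero1l held 2590 of 11785, 2712 of 12549 and 1354 of 12951 tumour-like cells in the vehicle libraries. In the A-196 libraries it held 1249 of 10677, 952 of 10165 and 1539 of 13435. Whether this make-up accounts for the hypoxia change was not tested. Type I interferon genes were lower in 25 of 28 (median −0.35, adjusted p = 5.8e-04, with Stat2 −0.50, Rtp4 −0.48, Irf9 −0.46), with 0 past the threshold adjusted over the list alone. Each of these was at adjusted p = 0.92 with an estimated correlation.

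The lists not called in EMT6 included the PERK to ATF4 arm (median −0.03, adjusted p = 0.72, with Slc3a2 −0.28, Atf4 −0.19), the IRE1 to XBP1 arm (0.03, adjusted p = 0.28, with Dnajc3 0.29), heat shock (0.04, adjusted p = 0.084, with Hspd1 0.33, Hsph1 0.44) and H4K20 regulators (0.00, adjusted p = 0.16, with Suv39h1 0.25, Orc1 0.43). MHC class I (−0.04, adjusted p = 0.084, with B2m −0.34, H2-K1 −0.36), MHC class II (0.35, adjusted p = 0.75), NF-kB (−0.11, adjusted p = 0.23, with Ccl2 −2.04) and type II interferon (median −0.09, mean 0.09, adjusted p = 0.70) did not pass either. Nor did cholesterol synthesis (−0.08, adjusted p = 0.11), dissociation stress (−0.14, 15 of 16 lower, adjusted p = 0.11), or extracellular matrix (median −0.12, mean 0.06 and test up, adjusted p = 0.70). The same held for ribosomal proteins (−0.03, adjusted p = 0.36), oxidative phosphorylation (0.04, adjusted p = 0.70, with Sdhb 0.31), p53 targets (median 0.01, mean −0.03, adjusted p = 0.70), spindle checkpoint (0.04, adjusted p = 0.49), fatty acid synthesis (−0.03, adjusted p = 0.72) and histone genes (0.08, adjusted p = 0.72).

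Averaged over both models Sgcb rose by 0.59 ± 0.08 (adjusted p = 0.019), the only gene of 13901 to pass. In 4T1 it went from 20.3 ± 1.77 to 24.4 ± 1.02 CPM (n = 3). The chitinase-like Chid1 came next at 0.49 ± 0.08 (adjusted p = 0.200), then Rexo2 at 0.30 ± 0.05 (adjusted p = 0.220). At an unadjusted p under 0.05 there were 922 genes, and DESeq2 called 8. In both models 100 genes (0.719%) were separated in the same direction, where chance gives 0.5% on average over groupings (spread not computed). The count was 0 when any of 9 libraries was left out and stayed 1 without 4T1 vehicle replicate 1, 4T1 vehicle replicate 2 or EMT6 A-196 replicate 2. Other groupings of the 12 libraries called up to 8 genes.

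All 17 ATF6 members were higher on average (median 0.13, adjusted p = 6.9e-07, and 0.92 with an estimated correlation). Sdf2l1 was higher by 0.30 ± 0.07, Hyou1 by 0.23 ± 0.07, Hsp90b1 by 0.25 ± 0.08 and Creld2 by 0.19 ± 0.06, and 6 passed adjusted over the list alone. IRE1 to XBP1 genes were higher in 15 of 20 (median 0.06, adjusted p = 0.0015, with Ern1 0.22, Dnajc3 0.20, Pdia6 0.21) and heat shock genes in 14 of 15 (median 0.06, adjusted p = 0.0039, with Hsph1 0.27, Hspd1 0.19), while the PERK to ATF4 list did not pass (median 0.03, adjusted p = 0.78). The share of tumour-like cells with a host UMI, not thinned to equal depth, was higher by 2.72 percentage points on average (exact stratified permutation p = 0.035). Of 18 host genes 14 were higher (median 0.21), none past the threshold. ATF6 transcripts were also abundant in fibroblast-like cells, at 5053 summed CPM in 4T1 vehicle tumours against 3321 ± 158 in tumour-like cells.

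**Figure D2:**
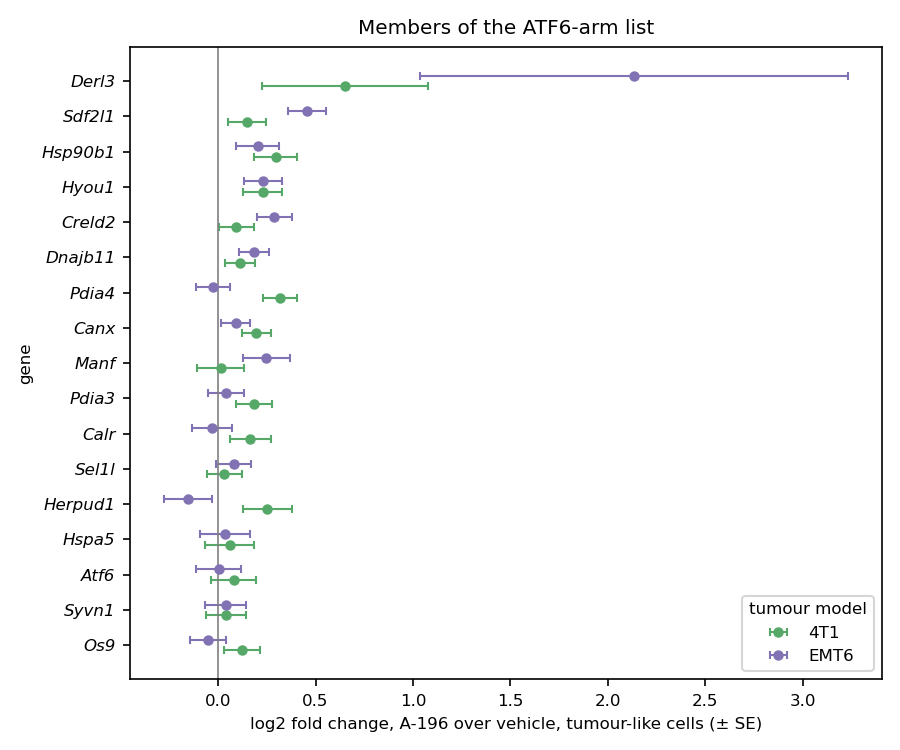
Log2 fold change of A-196 over vehicle (horizontal axis) for each of the 17 measured ATF6-arm genes in 4T1 and EMT6 tumour-like cells, with SE of the edgeR fit to 12 libraries. All 17 lie above 0 in 4T1 (median 0.15) and 13 in EMT6 (median 0.08).

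Cholesterol synthesis genes were lower on average in 20 of 22 (median −0.15, adjusted p = 6.9e-06, with Insig1 −0.20 and Idi1 −0.36), and 7 passed adjusted over the list alone. NF-kB genes were lower in 20 of 24 (median −0.23, adjusted p = 0.0047, with Cxcl1 −0.37, Nfkbiz −0.27, Tnfaip3 −0.26), and type I interferon genes in 25 of 28 (median −0.11, adjusted p = 0.0060). Ribosomal proteins were lower in 23 of 28 (median −0.07, adjusted p = 2.3e-04). Extracellular matrix genes were higher in 23 of 25 (median 0.17, adjusted p = 0.0030, with Serpinh1 0.24, P4hb 0.21). That made 8 lists (10 without EMT6 A-196 replicate 2), each with an adjusted p = 0.92 with an estimated correlation. Fry called 0, with 2 lists at an unadjusted p under 0.05, and other groupings of the same libraries called up to 20 lists. The S phase (median −0.02, adjusted p = 0.32), G2 (−0.01, adjusted p = 0.86), hypoxia (0.05, adjusted p = 0.72) and H4K20 (−0.01, adjusted p = 0.86) lists did not pass on average.

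Cenpv was the only gene whose response differed between models, with a difference (EMT6 minus 4T1) of 0.88 ± 0.12 (adjusted p = 0.036), and it went from 132 ± 9.35 to 113 ± 6.76 CPM in 4T1 (n = 3). Eno2 (−1.40 ± 0.23), Bnip3 (−1.13 ± 0.19), Wsb1 (−0.72 ± 0.12) and Tmem238 (0.81 ± 0.14) followed at adjusted p = 0.075. The count was 5 without EMT6 A-196 replicate 2, 3 without 4T1 vehicle replicate 1, 1 without EMT6 vehicle replicate 3 and 0 when any other library was left out. At an unadjusted p under 0.05 there were 1576 genes, DESeq2 called 214, and other groupings of the libraries called up to 23.

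All 41 S phase genes responded more positively in EMT6 than in 4T1 (median difference 0.40, adjusted p = 1.6e-10, with Gins2 0.61, Mcm5 0.60, Tyms 0.60), with 4 past the threshold adjusted over the list alone. Hypoxia genes differed the other way in 24 of 25 (median −0.48, adjusted p = 1.8e-09, with Ankrd37 −1.12, Car9 −1.03, Pdk1 −0.81), with 11 past it adjusted over the list alone. Without the shallow library these medians were 0.25 (adjusted p = 1.3e-05) and −0.40 (adjusted p = 2.50e-08). In all 9 lists differed (7 without that library), each at adjusted p = 0.92 with an estimated correlation. Fry called 0, with 3 lists at an unadjusted p under 0.05, and other groupings called up to 19 lists.

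**Figure D3:**
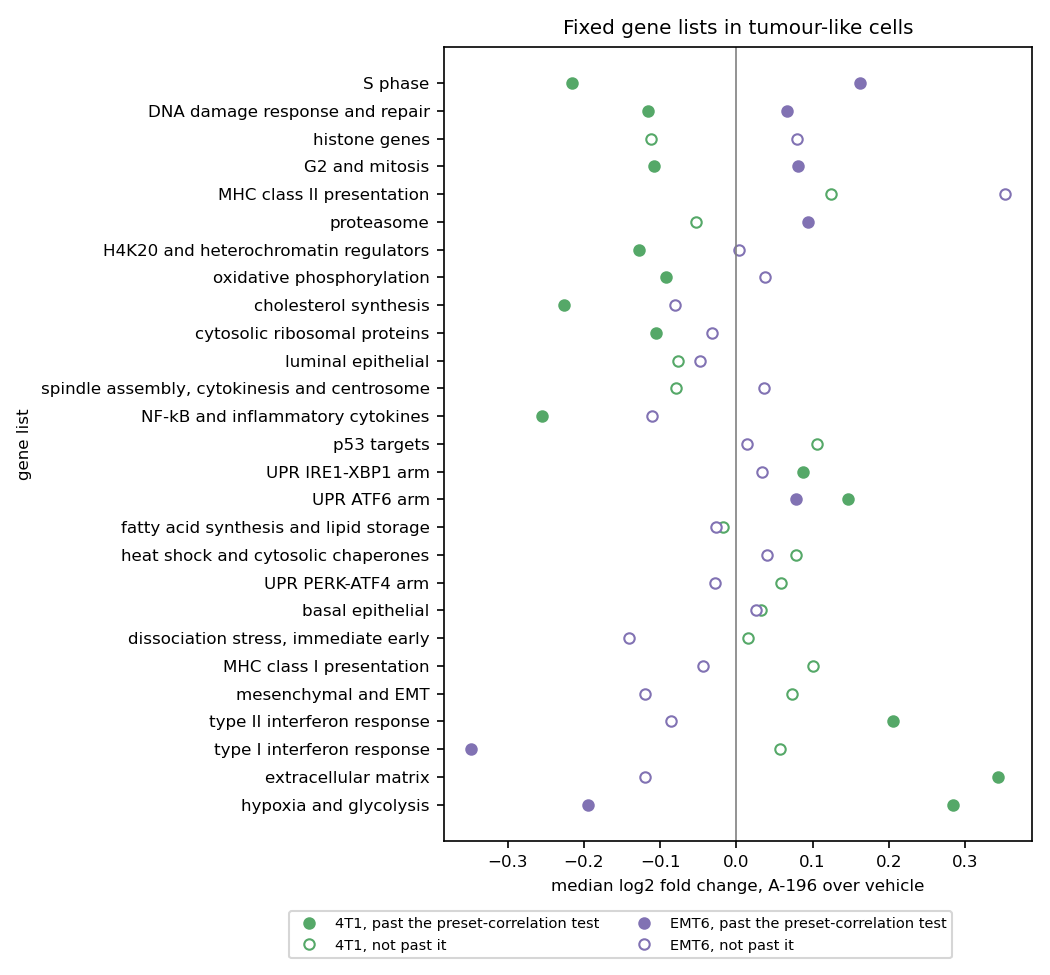
Median log2 fold change of A-196 over vehicle in tumour-like cells (horizontal axis) for the 27 tested gene lists, in 4T1 and EMT6 (3 vehicle and 3 A-196 libraries each, filled where past the preset-correlation test). S phase lies at −0.22 in 4T1 and 0.16 in EMT6, and hypoxia at 0.28 and −0.19.

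The target genes of A-196 did not pass the threshold. Kmt5b (chr19 3767421 to 3818303, plus strand) was at 26.5 ± 2.18 CPM in 4T1 vehicle and 28.2 ± 1.16 CPM in A-196 tumours (n = 3, 0.09 ± 0.10), and its EMT6 log2 fold change was −0.06 ± 0.11. Kmt5c (chr7 4740115 to 4747514, plus strand) was at −0.16 ± 0.12 in 4T1 and −0.02 ± 0.12 in EMT6. Kmt5a, the monomethyltransferase (chr5 124439930 to 124462308, plus strand), was at −0.11 ± 0.10 in 4T1 and 0.30 ± 0.10 in EMT6, where it went from 134 ± 7.77 to 165 ± 7.91 CPM (adjusted p = 0.302).

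Lineage genes did not pass as groups. The luminal list had a median of −0.08 in 4T1 (15 of 22 lower, adjusted p = 0.71) and −0.05 in EMT6 (mean −0.28, adjusted p = 0.81). Adjusted over the list alone Ovol1 passed upward in 4T1 (0.78 ± 0.17) and Spint1 downward in EMT6 (−0.46 ± 0.10). The basal list had a median of 0.03 in 4T1 (mean −0.01, adjusted p = 0.68, with Cdh3 0.97) and 0.03 in EMT6 (mean −0.05, test up, adjusted p = 0.31), where Itga6 (0.80 ± 0.19) passed adjusted over the list alone. Mesenchymal genes were at a median of 0.07 in 4T1 (22 of 27 higher, adjusted p = 0.099, with Fn1 0.42) and −0.12 in EMT6 (22 of 27 lower, adjusted p = 0.23, with Fn1 −0.38). On average the luminal, basal and mesenchymal medians were −0.05 (adjusted p = 0.67), 0.04 (adjusted p = 0.24) and 0.01 (adjusted p = 0.87).

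Keratin-positive shares of tumour-like cells were counted at 2000 UMIs per cell, and none passed the threshold. Luminal keratins were detected in 99.7% of 4T1 tumour-like cells in both groups, a measure too near its limit to show a rise, and in 72.7% ± 3.31 (vehicle) and 76.4% ± 3.41 (A-196) in EMT6 (n = 3, exact p = 0.3). In macrophage-like cells, which should lack them, the same measure gave 12.7%, 72.7% (11 cells) and 28.2% in the 4T1 vehicle libraries and 17.5% to 34.5% in 4T1 A-196. It gave 20.0% to 61.5% in EMT6 vehicle, from 94 cells, and 19.5% and 11.2% in EMT6 A-196, where replicate 2 had 0 such cells. Basal keratins were in 21.8% ± 7.88 and 18.0% ± 4.56 of 4T1 cells, and vimentin without keratin in 27.2% ± 3.21 and 23.6% ± 3.42 of EMT6 cells (n = 3, exact p = 0.3). Cycling cells were 28.05% ± 6.19 and 26.1% ± 2.79 in 4T1, and 34.6% ± 1.60 and 49.1% ± 25.5 in EMT6 (average exact p = 0.65), and no reading of division is made from them. In EMT6 A-196 replicate 2 only 50 of 10165 tumour-like cells reached 2000 UMIs, and 78.0% of these cycled. Without that library the average difference of 6.27 points became −0.960. In macrophage-like cells the same measure gave 51.3% and 44.1% in 4T1 and 56.5% and 56.5% in EMT6, where the A-196 value is the mean of replicates 1 and 3 only (68.0% and 45.0%). Tumour-like cells held 2.92 ± 0.496 and 2.63 ± 0.468 times the UMIs of macrophage-like cells in 4T1, and 3.23 ± 0.184 and 2.80 ± 1.26 times in EMT6 (average difference −0.359, exact p = 0.475), with 1.34 in EMT6 A-196 replicate 2 and an average difference of 0.0046 without it.

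In macrophage-like cells Phlda1 rose on average over both models. It went from 296 ± 24.7 to 555 ± 82.0 CPM in 4T1 and from 366 ± 25.2 to 548 ± 40.9 CPM in EMT6 (n = 3 each, average log2 fold change 0.74 ± 0.09, adjusted p = 0.016). Phlda1 (ENSMUSG00000020205) is a protein-coding gene at chr10 111506286 to 111508645 on the plus strand. Plk2 (1.24 ± 0.19, adjusted p = 0.091) and Phlda1 (0.90, adjusted p = 0.087) came closest in 4T1 alone. Of 11103 genes 0 passed in 4T1, in EMT6 and for the difference with edgeR, where 627, 493 and 403 had an unadjusted p under 0.05, and DESeq2 called 16 in all. The count of 1 became 20 without EMT6 A-196 replicate 2, 2 without 4T1 vehicle replicate 1 and 0 without 4T1 vehicle replicate 2, 4T1 vehicle replicate 3 or any EMT6 vehicle library, and other groupings of the libraries called up to 50.

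Inflammatory cytokine genes were higher in 4T1 macrophage-like cells. All 24 NF-kB genes were higher (median 0.48, adjusted p = 9.7e-10), with Ccl7 0.86 ± 0.18, Ccl2 0.86 ± 0.22 and Tnf 1.65 ± 0.44, and 4 passed adjusted over the list alone. The inflammatory activation list had the same median of 0.48 (13 of 15 higher, adjusted p = 5.2e-05), and hypoxia genes were higher in 22 of 25 (0.23, adjusted p = 8.4e-07). Tissue repair genes were higher in 17 of 20 (0.21, adjusted p = 0.0030, with Ctsl 0.69, Folr2 0.94), while S phase (−0.12, adjusted p = 0.040) and G2 genes (−0.13, adjusted p = 0.020) were lower. In EMT6 all 28 type I interferon genes were lower (median −0.40, adjusted p = 2.4e-05, with Ifit1 −0.62, Stat2 −0.58) and tissue repair genes were lower (−0.17, adjusted p = 0.039). In EMT6 A-196 replicate 2 a cluster led by Ccl8 and Mrc1 held 354 of the 768 macrophage-like cells, against 12 to 42 cells in the other EMT6 libraries. Without that library the type I interferon median was −0.22 (adjusted p = 0.0058). ATF6 genes were higher there in 14 of 16 (0.20, adjusted p = 9.2e-04, with Creld2 0.51, Hspa5 0.42). On average NF-kB (0.39, adjusted p = 9.0e-07, with Ptgs2 0.68 ± 0.16, Lif 0.63 ± 0.16), ATF6 (0.14, adjusted p = 9.0e-04, with Pdia4 0.33 ± 0.09), PERK (0.10, adjusted p = 0.041), inflammatory (0.36, adjusted p = 0.030) and hypoxia genes (0.11, adjusted p = 0.013) were higher. Type I interferon genes were lower on average (−0.16, adjusted p = 9.2e-05). With an estimated correlation every adjusted p was at least 0.885, and fry called 0. The 9 lists called were 5 without 4T1 vehicle replicate 2 and 11 without the shallow library, and other groupings called up to 12. With 1 library left out the S phase and G2 medians in 4T1 reached 0.024 and 0.010, and tissue repair in EMT6 reached 0.018. The IRE1, type II interferon, MHC class I and MHC class II lists were not called, and the MHC class II median was positive where the test pointed down in EMT6 and on average.

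In 4T1 neutrophil-like cells 4 genes changed of 6511. The chemokine Ccl7 rose from 13.7 ± 2.95 to 52.4 ± 11.8 CPM (n = 3, 1.94 ± 0.28, adjusted p = 2.3e-04, chr11 82045712 to 82047525, plus strand). Procr fell from 176 ± 60.7 to 82.8 ± 3.58 CPM (−1.13 ± 0.20, adjusted p = 0.013), Sfn from 381 ± 26.5 to 229 ± 23.1 CPM (−0.75 ± 0.15, adjusted p = 0.032) and Lif from 161 to 72.5 CPM (−1.06 ± 0.21, adjusted p = 0.037). Procr and Lif also lead a tumour-like cluster of 4T1, and Sfn is a marker of tumour-like cells. Ccl7 was more abundant in 4T1 macrophage-like cells, at 182 ± 17.5 CPM in vehicle and 330 ± 51.3 CPM in A-196 tumours (0.86 ± 0.18, adjusted p = 0.584). Ccl7 also differed between models (−2.62 ± 0.44, adjusted p = 0.0045, with EMT6 56.2 ± 17.9 to 37.5 ± 16.9 CPM). EdgeR called 0 genes in EMT6 and on average, where 349 and 328 had an unadjusted p under 0.05, and DESeq2 called 2 over the class. Without 4T1 vehicle replicate 1 only Ccl7 of these 4 was still called, with Procr at −0.76 (adjusted p = 0.258), Lif at −0.72 and Sfn at −0.69, and DESeq2 also kept 1 of the 4. The count of 4 was 1 without 4T1 A-196 replicate 2 and 0 without 4T1 A-196 replicate 3, 5 without the shallow library, and up to 30 in other groupings of the libraries.

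Neutrophil lists called in 4T1 were ATF6 (median 0.19, 15 of 16 higher, adjusted p = 0.0048, with Pdia4 0.64 ± 0.20), hypoxia (0.23, 20 of 25 higher, adjusted p = 6.6e-04, with Bnip3 0.68), type II interferon (0.20, 14 of 15 higher, adjusted p = 0.018, with Cxcl10 0.65) and immunosuppression (0.11, 11 of 16 higher, adjusted p = 0.038). In EMT6 type I interferon (−0.45, 16 of 18 lower, adjusted p = 0.018) and type II interferon genes (−0.66, 13 of 15 lower, adjusted p = 0.014, with Gbp2 −0.78 ± 0.20) were lower. The immunosuppression list was at a median of −0.110 with 1 library left out. The granule and immaturity list did not pass (−0.08 in 4T1, adjusted p = 0.80, and −0.10 in EMT6, mean −1.44, adjusted p = 0.052). Adjusted p with an estimated correlation was 0.519 or more, and fry called 0. The 5 lists called were 11 without 4T1 A-196 replicate 2, 9 without EMT6 vehicle replicate 2, 3 without EMT6 vehicle replicate 1 and up to 11 in other groupings.

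In 4T1 fibroblast-like cells 14 of 9170 genes changed (6 higher, 8 lower). The matrix protein gene Efemp1 rose from 36.4 ± 8.41 to 101 ± 3.53 CPM (n = 3, 1.45 ± 0.18, adjusted p = 6.7e-04, chr11 28853204 to 28926743, plus strand). So did the stromal glycoprotein gene Cd248 from 198 ± 6.16 to 298 ± 35.0 CPM (0.60 ± 0.12, adjusted p = 0.042) and Cyp1b1 from 54.6 to 117 CPM (1.10 ± 0.20, adjusted p = 0.042). Ccl4, which also leads a macrophage-like cluster of EMT6, rose by 1.31 ± 0.24 (adjusted p = 0.029). Fdx1 fell from 87.7 to 38.8 CPM (−1.16 ± 0.19, adjusted p = 0.020), Car12 by 1.46 ± 0.28 (adjusted p = 0.039) and Acp5 from 48.4 to 20.4 CPM (−1.25 ± 0.21, adjusted p = 0.022). Acp5 also fell on average (−1.05 ± 0.16, adjusted p = 0.026) and leads an osteoclast-like cluster. The average call was lost without any 1 of 7 libraries (4T1 vehicle replicates 1 and 2, 4T1 A-196 replicate 3, EMT6 vehicle replicates 1 and 2, EMT6 A-196 replicates 1 and 2), with values of −0.876 to −1.08, and with tumour numbers as a block (adjusted p = 0.064). EdgeR called 0 genes in EMT6 and for the difference, with 597 and 687 at an unadjusted p under 0.05. The 14 became 1 without 4T1 vehicle replicate 2, 6 without 4T1 vehicle replicate 1 or 4T1 A-196 replicate 3, 7 without EMT6 vehicle replicate 1, 9 without 4T1 vehicle replicate 3, 13 without the shallow library, and up to 35 in other groupings of the libraries.

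Fibroblast complement and inflammatory genes were higher in 4T1 in 12 of 15 (median 0.23, adjusted p = 0.0015), as were ATF6 (0.17, adjusted p = 0.0036, with Creld2 0.35, Pdia4 0.32), PERK (0.12, adjusted p = 0.014), NF-kB (0.17, adjusted p = 0.017, with Tnf 1.00) and all 6 MHC class II genes (0.48, adjusted p = 0.017). In EMT6 the G2 list was higher in 31 of 39 (0.33, adjusted p = 3.0e-07, with Top2a 0.64, Cdk1 0.77) and the S phase list in 22 of 27 (0.26, adjusted p = 2.3e-04, with Tyms 0.57), while NF-kB was lower (−0.11, adjusted p = 0.022). On average ATF6 (0.13, adjusted p = 0.0052), S phase (0.12, adjusted p = 7.4e-04), G2 (0.15, adjusted p = 1.1e-05) and MHC class II (0.32, adjusted p = 0.037) were higher and type I interferon lower (−0.15, adjusted p = 0.042). With 1 library left out the NF-kB median reached −0.030 in 4T1 and 0.066 in EMT6, and the average type I interferon median 0.027. The contractile list did not pass (−0.04 in 4T1, adjusted p = 0.23, and 0.10 in EMT6, adjusted p = 0.76). With an estimated correlation every adjusted p was 0.991, and fry called 0. The 8 lists called were 5 without 4T1 vehicle replicate 2 and up to 12 in other groupings.

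T and NK-like cells could be tested in 4T1 only (6 libraries, 4146 genes), and 3 genes changed. Il1rn rose from 38.0 to 102 CPM (1.51 ± 0.33), the replication gene Pclaf rose from 99.7 to 218 CPM (1.05 ± 0.23), and Cebpb fell by 0.68 ± 0.14 (adjusted p = 0.032 each). Among genes of tumour-like cells, chosen after their values were seen, Krt8 fell by 0.50 ± 0.14 (adjusted p = 0.135), Krt7 by 0.74 ± 0.23 (adjusted p = 0.339) and Lad1 by 0.80 ± 0.27 (adjusted p = 0.312) in the same cells. Mitotic genes were higher in 25 of 27 (median 0.45, adjusted p = 1.3e-06, with Ube2c 0.88 ± 0.21, Mki67 0.65), with 9 past the threshold adjusted over the list alone. S phase (0.29, adjusted p = 0.013), type II interferon (0.33, adjusted p = 0.023) and regulatory T genes (0.47, 8 of 9 higher, adjusted p = 0.023, with Ctla4 0.64, Foxp3 0.87) were higher. The cytotoxicity (−0.08, adjusted p = 0.67), exhaustion (median −0.06, mean −0.02, test up, adjusted p = 0.98) and naive and memory genes (0.19, adjusted p = 0.42) were not called. With an estimated correlation the smallest adjusted p was 0.291, fry called 0, and DESeq2 called 0 genes. The gene count was 13 without 4T1 vehicle replicate 2 or 4T1 A-196 replicate 3, 12 without 4T1 A-196 replicate 1, 6 without 4T1 vehicle replicate 1, 2 without 4T1 A-196 replicate 2 and up to 4 in other groupings of these libraries. Without 4T1 vehicle replicate 3 only 1 of the 3 genes remained. The 4 lists were 2 without 4T1 A-196 replicate 3 and up to 4 in other groupings.

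Spp1 (osteopontin) changed in opposite directions in endothelial-like cells (11 libraries, 4840 genes). It rose from 848 ± 128 to 1471 ± 279 CPM in 4T1 (0.79 ± 0.15, adjusted p = 0.012). It fell from 1153 ± 223 to 569 ± 157 CPM in EMT6 (A-196 replicates 1 and 3 only, −1.04 ± 0.20, adjusted p = 0.011). The difference was −1.83 ± 0.25 (adjusted p = 1.1e-05, chr5 104435118 to 104441050, plus strand). Whether this Spp1 RNA arose in endothelial-like cells or was carried over from other classes was not tested. In EMT6 Klf4 (−1.35 ± 0.28, adjusted p = 0.019), Fth1 (−0.75 ± 0.14, adjusted p = 0.0049) and Mt2 (−1.24, adjusted p = 0.049) fell. On average Lyve1, a lymphatic marker that also leads a macrophage-like cluster of 4T1, fell by 1.91 ± 0.38 (adjusted p = 0.048). It went from 47.0 to 19.1 CPM in 4T1 and from 135 to 27.3 CPM in EMT6 (chr7 110850607 to 110863239, minus strand). Without EMT6 A-196 replicate 1 none of the 4 EMT6 calls remained and Lyve1 on average was at −1.36 (adjusted p = 0.244), and without EMT6 A-196 replicate 3 or EMT6 vehicle replicate 3 only 1 of the 4 remained. DESeq2 kept 2 of the 4 and did not call Lyve1 (adjusted p = 0.193). The 5 genes became 18 without 4T1 A-196 replicate 3, 10 without 4T1 A-196 replicate 2 and 3 without EMT6 vehicle replicate 1 or EMT6 vehicle replicate 3. DESeq2 called 17, other groupings of the libraries called up to 5, and EMT6 A-196 replicate 2 had too few endothelial-like cells to enter.

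Endothelial hypoxia genes were higher in 4T1 in 22 of 23 (median 0.25, adjusted p = 1.1e-05, with Ero1l 1.08, Egln3 1.19) and lower in EMT6 in 19 of 23 (−0.47, adjusted p = 2.1e-04, with Ldha −0.56). In 4T1 all 13 type II interferon genes were higher (0.55, adjusted p = 3.2e-05, with Irf1 0.85 ± 0.20, Gbp2 0.78), with 4 past the threshold adjusted over the list alone, as were ATF6 (0.20, adjusted p = 0.022), NF-kB (0.24, adjusted p = 0.033, with Icam1 0.62) and angiogenic genes (0.29, adjusted p = 0.022, with Apln 1.00 ± 0.24, Esm1 0.81). In EMT6 type I interferon (−0.44, adjusted p = 0.022) and MHC class I genes (−0.33, adjusted p = 0.015) were lower. On average ATF6 was higher (0.19, adjusted p = 0.033) and type I interferon lower (−0.33, adjusted p = 0.015). Adjusted p with an estimated correlation was 0.251 or more, and fry called 0 lists in either model or on average and 1 for the difference (hypoxia, adjusted p = 0.049). The MHC class I median in EMT6 reached 0.095 with 1 library left out. The 7 lists called were 3 without 4T1 A-196 replicate 1 and up to 9 in other groupings. Classes of the same tumours are not independent of each other.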

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

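The tests of host-cell RNA, scaling and a single library for the ATF6 genes, of the shallow library for the S phase and hypoxia genes, and the counts over all 27 lists for these 3 lists were chosen only after those results were seen; the other counts of groupings were set before.

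The ATF6 genes were higher with A-196 in tumour-like cells on average (all 17, median 0.13). Regrouping the libraries excluded chance for this list alone (2 of 100 groupings, the real one included, reached the real median of 0.131, highest other 0.154), but in 59 of 100 some list of the 27 lay as far from 0 (standardised 2.26), so chance was not excluded once the choice of list is counted. The lowest median with 1 library left out, 0.113, speaks against a single library, while scaling stays open because it centres the genes and so fixes their median (−0.0021). Fibroblast-like RNA, the richest in this list of the host classes compared, would need its markers to rise by 12564 CPM in 4T1 where they rose by 21.8 CPM, and macrophage-like, neutrophil-like, T and NK-like and endothelial-like RNA held the list near or below the tumour-like level, which speaks against RNA of these classes, alone or mixed, as the main source; other host classes were not tested. Leaving out cells with a host UMI decides nothing, because the other host genes then stayed higher (median 0.37), and with an adjusted p of 0.92 at an estimated correlation a change of the cells themselves stays open.

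The S phase genes were lower in 4T1 and higher in EMT6 (difference 0.40). Chance was excluded for this list alone (1 of 100 groupings, real value 0.405, highest other 0.392) but not with the choice among 27 lists counted (68 of 100 held a list as far from 0, standardised 2.11). Without the shallow EMT6 A-196 replicate 2 the EMT6 median was 0.028, so the EMT6 rise may come from that library alone, while the 4T1 side did not involve it.

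The hypoxia genes were higher in 4T1 and lower in EMT6 (difference −0.48). Chance was excluded for this list alone (2 of 100 groupings, real value −0.478, highest other −0.533) but not with the choice among 27 lists counted (54 of 100, standardised −2.32). Without the shallow library the EMT6 median was −0.099 and still past the threshold, so that library may add to the size but not to the direction. Tumour size and oxygen supply at harvest were not analysed here and remain open.

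Other results drew attention because their difference between models (EMT6 minus 4T1) passed the threshold, for lists with the preset correlation. In tumour-like cells Cenpv differed by 0.88. H4K20 and heterochromatin regulators differed by 0.15, the proteasome by 0.15, type I interferon by −0.41, MHC class I by −0.20, G2 and mitosis by 0.20, DNA damage by 0.20 and oxidative phosphorylation by 0.11. Of 100 groupings, the real one included, 9 gave an H4K20 median as far from 0 and 9 a proteasome median. Type I interferon was reached in 29, MHC class I in 23, G2 and mitosis in 15, DNA damage in 8 and oxidative phosphorylation in 22. Chance was not excluded for any of these lists. In macrophage-like cells type I interferon differed by −0.38, S phase by 0.16, G2 by 0.10, hypoxia by −0.33, NF-kB by −0.14, tissue repair by −0.45 and inflammatory activation by −0.33. In neutrophil-like cells Ccl7 differed by −2.62, type I interferon by −0.73, type II interferon by −0.79 and hypoxia by −0.27. In fibroblast-like cells S phase differed by 0.24, G2 by 0.41, NF-kB by −0.26 and inflammatory and complement genes by −0.42. In endothelial-like cells Spp1 differed by −1.83, type II interferon by −0.50, MHC class I by −0.38, hypoxia by −0.67 and NF-kB by −0.56. By camera with an estimated correlation no list of any class passed for the difference (smallest adjusted p = 0.251, in endothelial-like cells). Outside tumour-like cells groupings were not counted list by list.

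Counts of genes were compared with other groupings (splits) of the same libraries, and each number of splits includes the real one. In 4T1 tumour-like cells the real count was 0, which any split reaches, so the comparison decides nothing (10 of 10, highest other 10). In EMT6 tumour-like cells 2 of 10 splits called as many genes as the real 4 (highest other 44), and these splits are too few to decide. For the average 9 of 100 splits reached the real 1 (highest other 8) and for the difference 8 of 100 reached the real 1 (highest other 23), so chance was not excluded. It was not excluded in macrophage-like (20 of 100, real 1, highest other 50), neutrophil-like (24 of 100, real 4, highest other 30) or fibroblast-like cells (7 of 100, real 14, highest other 35) either. In T and NK-like cells 4 of 10 splits reached the real 3 (highest other 4), too few splits to decide. In endothelial-like cells 3 of 100 splits reached the real 5 (highest other 5), which excludes chance for this class alone but does not count the choice among the classes compared. Splits that call several times the real count, as in EMT6 tumour-like and macrophage-like cells, point to a structure of the samples, whose cause was not tested.

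Counts of lists did not stand out from other groupings. In tumour-like cells 3 of 10 splits reached the real 13 in 4T1 (highest other 15), too few to decide. In EMT6 10 of 10 reached the real 7 (highest other 14), so chance was not excluded. For the average 82 of 100 reached the real 8 (highest other 20) and for the difference 71 of 100 the real 9 (highest other 19), so chance was not excluded. The same held for macrophage-like (45 of 100, real 9, highest other 12), neutrophil-like (58 of 100, real 5, highest other 11), fibroblast-like (54 of 100, real 8, highest other 12) and endothelial-like cells (20 of 100, real 7, highest other 9). In T and NK-like cells 2 of 10 splits reached the real 4 (highest other 4), too few to decide. The smallest list p of any split was 1.6e-24 against the real 1.5e-12, and 64 of 100 reached the real one. The largest standardised median over all 27 lists was 3.61 on average (NF-kB, 3 of 100, highest other 3.90). This excludes chance for the average alone but does not count the choice among the contrasts compared. For the difference the largest was 2.36 (54 of 100, highest other 3.91), where chance was not excluded.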

How the results depend on the processing

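Main settings, lists and most alternatives were fixed before the data were examined. RLE scaling and removal of cells with a host UMI for the lists, and leaving the shallow library out at 1000 UMIs, were chosen only after results were seen. Without leaving libraries out, 38 gene counts stayed within 1.5 times and 31 moved further, and 16 list counts stayed and 19 moved; 239 list medians kept direction and call, 208 weakened and 1 reversed. For named genes 1045 values stayed, 131 were stronger, 28 weaker and 2 reversed. With a library left out, 58 gene counts stayed and 49 moved, 93 list counts stayed and 8 moved, and 1105 list medians stayed, 198 weakened, 4 were stronger and 47 reversed. For named genes 1730 stayed, 56 were stronger, 136 weaker and 6 reversed. Shares kept their direction in 94 alternatives and reversed in 7, and with a library left out in 194 and 10.

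An estimated correlation and fry both called 0 lists in tumour-like cells for 4T1, EMT6, the average and the difference, and 0 in macrophage-like, neutrophil-like, fibroblast-like, T and NK-like and endothelial-like cells in either model or on average; for the difference fry called 1 in endothelial-like cells.

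DESeq2 called 35 tumour-like genes in 4T1, 138 in EMT6, 8 on average and 214 for the difference, and 16 in macrophage-like, 2 in neutrophil-like, 0 in T and NK-like and 17 in endothelial-like cells. Without an expression filter the tumour-like counts were 5 in 4T1, 19 in EMT6, 2 on average and 35 for the difference, and 4 in macrophage-like, 14 in neutrophil-like, 129 in fibroblast-like, 15 in T and NK-like and 14 in endothelial-like cells. With log2 CPM of at least 4 the average was 0 and the difference 4. A separate fit of EMT6 called 0. The stricter cell filter called 8 in EMT6 and 2 for the difference, no doublet removal 7 in EMT6, Leiden 0.5 called 0 for the difference, and an equal number of tumour-like cells 0 on average. Kmt5b on average was −0.0060 with cells that held a host UMI left out, and Kmt5c in EMT6 was 0.033 with an equal number of cells. Apart from the filters, which change the genes tested, the cause was not tested.

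With the tumour number as a replicate block the tumour-like average was 0 genes and the difference 14, the mesenchymal and EMT list on average turned to −0.0017, macrophage-like cells gave 0 genes, neutrophil-like cells 10 genes and 8 lists, fibroblast-like cells 22 genes and endothelial-like cells 18. Correlations of vehicle and A-196 tumours with the same number were 0.0021, −0.123 and −0.0551 in 4T1 and 0.202, −0.0588 and 0.258 in EMT6. Tumours with different numbers gave −0.106 to 0.163 in 4T1 and −0.314 to 0.218 in EMT6. Block values thus rest on a pairing that the data do not show in 4T1 and do not settle in EMT6.

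With each library left out in turn, tumour-like genes in EMT6 ranged from 0 (without EMT6 vehicle replicate 1) to 14 (without EMT6 A-196 replicate 2), on average from 0 (without 4T1 vehicle replicate 3) to 1, and for the difference from 0 (without 4T1 vehicle replicate 2) to 5 (without EMT6 A-196 replicate 2). Lists called in EMT6 ranged from 6 to 11 (without EMT6 vehicle replicate 3). Macrophage-like genes ranged from 0 (without 4T1 vehicle replicate 2) to 20 (without EMT6 A-196 replicate 2) and lists from 5 to 11. Neutrophil-like genes ranged from 0 (without 4T1 A-196 replicate 3) to 6 and lists from 3 (without EMT6 vehicle replicate 1) to 11 (without 4T1 A-196 replicate 2). Fibroblast-like genes ranged from 1 (without 4T1 vehicle replicate 2) to 16 and lists from 5 to 9. T and NK-like genes ranged from 2 to 13 (without 4T1 vehicle replicate 2) and lists from 2 to 4. Endothelial-like genes ranged from 3 (without EMT6 vehicle replicate 1) to 18 (without 4T1 A-196 replicate 3) and lists from 3 (without 4T1 A-196 replicate 1) to 9. Fewer samples can lower counts, but the cause of lower or higher counts was not tested.

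Several values near 0 turned with a library left out, and the cause was not tested. In tumour-like cells Kmt5a in 4T1 ranged from −0.203 to 0.0013, Kmt5c in EMT6 from −0.083 to 0.071, Kmt5b in EMT6 from −0.158 to 0.034 and on average from −0.032 to 0.064. The luminal list ranged from −0.193 to 0.013 in 4T1, from −0.229 to 0.120 in EMT6 and from −0.107 to 0.025 on average, and the basal list from −0.090 to 0.085, from −0.063 to 0.469 and from −0.019 to 0.143. The PERK list ranged from −0.250 to 0.098 in EMT6 and from −0.076 to 0.092 on average, IRE1 in EMT6 from −0.029 to 0.052, DNA damage in EMT6 from −0.0020 to 0.147, and the mesenchymal list on average from −0.041 to 0.046.

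In macrophage-like cells S phase ranged from −0.251 to 0.024 in 4T1 and from −0.030 to 0.276 for the difference, G2 in 4T1 from −0.279 to 0.010 and tissue repair in EMT6 from −0.580 to 0.018. Immunosuppression in 4T1 neutrophil-like cells ranged from −0.110 to 0.323. In fibroblast-like cells NF-kB ranged from −0.030 to 0.446 in 4T1 and from −0.403 to 0.066 in EMT6, and type I interferon on average from −0.370 to 0.027. In endothelial-like cells MHC class I in EMT6 ranged from −0.816 to 0.095 and type II interferon for the difference from −1.66 to 0.042. The cause was not tested.

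Shares turned too. With host cells as denominator T and NK-like cells were at −0.303 points in 4T1 and pericyte-like cells at −0.0078 on average. At 4000 UMIs the cycling share was −7.01, basal keratin 0.326 and both keratins 0.346, and unthinned the luminal keratin share was −0.969 and vimentin without keratin 1.05. With a library left out 4T1 T and NK-like cells ranged from −0.224 to 0.197 points and adipocyte-like from −0.0261 to 0.0096, and on average neutrophil-like from −0.389 to 0.474, pericyte-like from −0.0355 to 0.212, cycling cells from −0.960 (without EMT6 A-196 replicate 2) to 11.1, and the UMI ratio from −0.542 to 0.0046 (without EMT6 A-196 replicate 2). The cause was not tested.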

Other observations

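The comparison of vehicle EMT6 with vehicle 4T1 tumour-like cells and its alternatives were chosen only after the data were seen; the lysosomal test was set before its result. The vehicle-treated models differed in 9158 of 13901 genes (4569 higher and 4589 lower in EMT6, 9555 at an unadjusted p under 0.05). DESeq2 called 8949, RLE scaling 9154, no filter 9369, and 8427 to 8826 were called with 1 vehicle library left out. 4T1 cells expressed epithelial genes that EMT6 cells nearly lacked. Cldn7 was at 201 ± 74.7 CPM in 4T1 and 0.0561 CPM in EMT6, Cldn3 at 181 ± 62.4 and 0.0593 CPM, Fgfr2 at 88.8 ± 5.62 and 0.0428 CPM, and the luminal factor Gata3 at 70.9 ± 2.81 and 1.12 CPM (SD, n = 3). The luminal list was lower in EMT6 in 21 of 22 members (median −6.15, adjusted p = 1.4e-10, and 0.162 with an estimated correlation), and 20 passed adjusted over the list alone.

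Mesenchymal genes were higher in EMT6 in 19 of 27 and lower in 8 (median 1.32, adjusted p = 0.0072, and 0.648 with an estimated correlation). Prrx1 was at 67.0 ± 4.77 CPM in EMT6 and 0.472 CPM in 4T1, Vim at 9675 ± 450 and 5467 ± 978 CPM, and Col5a1 at 146 and 28.8 CPM. Cdkn2a was at 58.1 ± 3.02 CPM in EMT6 and 0.0247 CPM in 4T1. Cholesterol synthesis genes were higher in EMT6 in all 22 (median 1.44, adjusted p = 7.3e-09, and 0.217 with an estimated correlation), p53 targets in 16 of 21 (median 0.94, adjusted p = 0.011, and 0.162 with an estimated correlation), and MHC class II genes were lower in all 10 (median −2.60, adjusted p = 0.017, and 0.775 with an estimated correlation). Of the 10 splits of these 6 libraries 1 called as many as the real 9158 genes (highest other 0). The splits alone are too few to exclude chance. The 9158 called genes, 4185 of them at least 2-fold, argue against it, as 8427 or more were called with any 1 vehicle library left out.

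Lysosomal enzymes among the genes with the smallest p in 4T1 led to the hypothesis that lysosomal genes rise together with A-196. Without the genes that prompted it, the list of 40 gave p = 0.0651 (camera, estimated correlation) in 4T1, with 38 of 40 higher (median 0.20, fry p = 0.026). In EMT6 camera with an estimated correlation gave p = 0.323, and 31 of 40 members were lower (median −0.11), which is against a rise there. The bound set beforehand counted any p over 0.05 as evidence against a rise. That bound was wrong, since such a p excludes nothing while 38 of 40 members are higher. The 4T1 case stays open. Host-cell RNA as a source of the lysosomal change was not tested. In the same comparison the share of tumour-like cells with a host UMI was 3.76 percentage points higher (exact p = 0.1, the smallest possible).

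Nuclear-RNA-led clusters without a class were 1.98% ± 0.733 of vehicle and 2.73% ± 1.96 of A-196 cells in 4T1 (2865 cells; n = 3, exact p = 0.6) and 2.68% ± 2.78 and 3.98% ± 2.31 in EMT6 (3743 cells, exact p = 0.5). Clusters led by the osteoclast genes Ctsk, Acp5, Atp6v0d2 and Ocstamp were 0.198% and 0.196% in 4T1 (253 cells), and 3.00% ± 1.13 and 1.54% ± 1.03 in EMT6 (2310 cells; n = 3, exact p = 0.2). Another EMT6 cluster mixed plasmacytoid and T cell genes (245 cells; 0.192% and 0.242%).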
